A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

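Gene expression was measured in the wine yeast Saccharomyces cerevisiae EC1118 with 1-colour Cy3 oligonucleotide arrays hybridised with total RNA. The series held 16 arrays from 15 samples. Of these, 4 samples came from the stationary phase of batch fermentations, 4 from the third stage of a continuous fermentation without nitrogen addition, 3 from that stage with added ammonium and 3 with added valine. Ammonium sample 3 was hybridised on both slides, and its 2 arrays were averaged before any test. The remaining sample carried labels that name ammonium in 2 fields and valine in the others, so it was assigned to no group and left out of every comparison. Arrays lay on 2 slides, and each slide held all 4 groups. Slide 1 held 3 batch arrays, 1 without addition, 1 with ammonium and 2 with valine, and slide 2 held 1, 3, 3 and 1.

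The deposited values are log2 intensities per probe, and the submitters' processing notes name R 2.13.1 and limma. The log2 scale was read from the values themselves. Array medians lay between 9.09 and 9.10, array minima between 5.50 and 5.56, and array maxima between 15.82 and 15.96, so that all arrays had almost the same distribution. The method of normalization, the background correction and the averaging of spots are not given in the sources used here. Scale and centring are therefore known only as far as these distributions show them. The direction of a difference is that of single-dye intensities, relative to the whole of each array. A change in total mRNA between conditions would not be seen, so the sign of a small difference can depend on the normalization. No flags of detection came with the values, and genes near the minimum have compressed fold changes. Fold changes of genes near the maximum can be compressed as well. The number of arrays limits the precision of every value.

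Of 6271 probes, 5220 carried 1 gene symbol, 1051 carried none and 0 carried several. Among the symbols 5167 were current, 51 were updated and 2 matched no current gene. Probes of the same gene were averaged, which left 6248 features, of which 4783 had a gene name other than a systematic one. No filter on intensity was used.

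Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of the 14 samples with 1 mean per group and 10 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 6248 features of a comparison. The comparisons were the third stage without addition against batch, each supplement against no addition, and ammonium against valine. Differences are given as log2 fold changes with their standard error from limma. Levels are group means of log2 intensity with the SD between samples. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

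Before the data were examined, 36 gene lists were fixed from textbook knowledge, each with at least 4 measured members, and tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists. The lists covered nitrogen catabolite repression targets, central nitrogen metabolism, amino acid permeases, the synthesis of branched-chain amino acids, lysine, arginine, aromatic amino acids with histidine, and sulfur amino acids, one-carbon and purine metabolism, the Ehrlich pathway, aroma esters, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, tRNA synthetases, stress genes, trehalose and glycogen, glycolysis and fermentation, hexose transporters, the TCA cycle, respiration, anaerobic genes, the PAU family, ergosterol, fatty acid synthesis, thiamine, autophagy and the vacuole, the proteasome, cell cycle and replication, histones, glycerol, the iron regulon, the phosphate regulon, meiosis and sporulation, haploid mating, and the mitochondrial genome. The tests were repeated with a correlation estimated from the data and with the rotation test fry. The number of called members was also taken with p adjusted over the list alone.

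Genes to be named were set by a rule fixed at the same time: for each comparison the 5 named genes with the largest positive and the 5 with the largest negative change among called genes without overlap between groups, the 3 members with the smallest adjusted p of each list past its threshold, and a panel of 19 genes. The panel was GAP1, MEP2, DAL80, GDH1, GLN1, BAT1, BAT2, ILV5, LYS20, ARO10, PDC1, ATF1, HSP12, HSP26, TSL1, HXT1, HXT6, CYC1 and THI4. Members that make up a count of 5 or fewer, and the genes opposed between supplements, were named after their values were seen. So were 4 further lists, of daughter-specific and other cell wall genes, beta-oxidation, gluconeogenesis with the glyoxylate cycle, and aryl-alcohol dehydrogenases.

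Both supplements share the no-addition samples, so the overlap of their responses was set beside 100 simulations of unchanged groups against shared controls and beside the 6 ways of giving each supplement a separate pair of controls. Alternatives fixed beforehand were median centring, renewed quantile normalization, leaving out the dimmest 25% of genes, the highest probe per gene, slide as a block, each slide alone, the replicate number as a block, each pair of groups fitted alone, either array of ammonium sample 3 alone, an intensity trend with a robust prior, array weights, stricter thresholds, and leaving out each sample in turn. A pair of alternatives was added after seeing the data: leaving out together 3 samples that stood apart from their groups, and removing each sample's trend with gene length over the 5195 genes with a known length. Other splits of the samples between groups were counted.

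The fit was tested on simulated data with 200 changed genes. Changes of 1 on the log2 scale were recovered in 98.5% to 100% of cases and changes of 0.5 in 88.1% to 95.5%, while between 8 and 18 unchanged genes were called. The simulated noise was independent between genes and samples, and far fewer genes changed than were called in most comparisons. In the data, deviations of batch sample 1 and valine sample 3 from their groups correlated at 0.646 across genes. The number of false calls in the data can therefore differ.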

Results

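Expression profiles were obtained from EC1118, a commercial diploid wine strain of Saccharomyces cerevisiae, in a synthetic must that held glucose at 200 g/L and nitrogen at 100 mg/L. The continuous fermentation ran through 4 tanks in series, and in the third tank resting cells had used up the nitrogen at 164 g/L residual glucose. Batch cultures at 28 °C were sampled in stationary phase at the same residual glucose. Ammonium or valine then fed into the third tank added 100 mg/L nitrogen. The sample labels give no temperature for the continuous culture and no residual glucose with a supplement, so whether these matched is not known. There were 4 batch samples, 4 without addition, 3 with ammonium and 3 with valine, measured on 15 arrays whose median log2 intensities lay between 9.09 and 9.10. Samples of each continuous condition were taken 24 h apart from a running culture, and whether the 4 batch samples came from separate fermentors is unclear. The p-values therefore measure spread between samplings, which can be technical, and condition cannot be separated from the time of the run. Ammonium sample 3 gives a measure of array noise: its 2 arrays differed with an SD of 0.17 on the log2 scale over genes. They lay on different slides, so this value includes any slide difference. Pairs of samples within a group differed with an SD of 0.11 to 0.30, and 12 of 20 such pairs differed less than those 2 arrays. Pairs of samples between groups differed with an SD of at least 0.24.

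The first comparison asked how resting cells in the third stage differed from batch cells that had consumed as much sugar. The largest increase was in DSE4, a daughter-specific glucanase, at 10.40 ± 0.08 (SD, n = 4) against 6.67 ± 0.17 (n = 4) in batch, a log2 fold change of 3.74 ± 0.07 (SE). The cell wall genes EGT2 (3.06 ± 0.08), TIR3 (3.48 ± 0.33) and DAN1 (3.03 ± 0.45) were higher as well, as was THI4 of thiazole synthesis (3.03 ± 0.27, and 2.64 without no-addition sample 4). Batch samples parted in DAN1, at 10.14 and 10.09 in samples 1 and 2 but 7.73 and 7.90 in samples 3 and 4, and in TIR3, at 9.63 and 9.87 against 8.09 and 8.22, so the size of these differences depends on the batch samples taken. Genes of ribosome production were lower, with the RNA helicase DBP2 at the extreme (-3.35 ± 0.14). Further genes at the low end were PRM7 (-2.47 ± 0.13), IMD4 of guanine nucleotide synthesis (-1.88 ± 0.13), the adenine deaminase AAH1 (-1.87 ± 0.14) and NOG2, needed for export of the large ribosomal subunit (-1.85 ± 0.17).

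The machinery that builds ribosomes was lower in the third stage in nearly all its parts. Of 104 ribosome biogenesis genes 103 were lower, with a median log2 fold change of -1.03 (camera adjusted p = 3.19e-36, and adjusted p = 0.169 with an estimated correlation). HAS1 (-1.71) and NOP1 (-1.46) were among them, and RMP1 at 0.12 was the member without a call. Ribosomal proteins were lower in 126 of 135 genes, with a median of -0.60 (adjusted p = 8.05e-27, and adjusted p = 0.169 with an estimated correlation), such as RPS4A (-0.75 ± 0.05) and RPL16B (-0.77 ± 0.06). Subunits of RNA polymerases I and III, which transcribe rRNA and tRNA, were lower in 21 of 24 cases, with a median of -0.55 (adjusted p = 4.39e-09, and adjusted p = 0.128 with an estimated correlation). Among 18 tRNA synthetases 14 were lower and 2, GUS1 and TYS1, were higher, with a median of -0.34 (adjusted p = 0.00456, and adjusted p = 0.754 with an estimated correlation). KRS1 (-1.05) and FRS2 (-0.66) were lower.

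Uptake genes for amino acids and iron were lower too. Of 20 amino acid permease genes 13 were lower and 1, TAT1, was higher, with a median of -0.38 (adjusted p = 7.68e-04, and adjusted p = 0.223 with an estimated correlation). The high-affinity methionine permease MUP1 (-1.25 ± 0.09), SAM3 (-0.87) and the lysine permease LYP1 (-0.70) were examples. In the iron regulon 13 of 21 genes were lower and 2, ENB1 and the vacuolar transporter SMF3 (0.74), were higher, with a median of -0.26 (adjusted p = 0.0154, and adjusted p = 0.128 with an estimated correlation). The low-affinity iron transporter FET4 was at -0.88 ± 0.09.

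Proteasome genes, reserve carbohydrate genes and part of the stress genes were higher. Proteasome subunits were higher in 29 of 33 cases and lower in 0, with a median of 0.49 (adjusted p = 2.76e-10, and adjusted p = 0.128 with an estimated correlation), among them RPN12 (0.86 ± 0.05) and PUP2 (0.78). Of 36 general stress and heat shock genes 19 were higher and 4 lower (HSP30, SSA3, SSA4 and GRE1), with a median of 0.32 (adjusted p = 0.0095, and adjusted p = 0.784 with an estimated correlation). The aldose reductase GRE3 (1.69 ± 0.12), the nicotinamidase PNC1 (1.28) and HSP12 (1.07 ± 0.09) were higher, whereas HSP26 at -0.10 ± 0.15 was not called. In trehalose and glycogen metabolism 12 of 17 genes were higher and 2, GLG2 and GAC1, lower, with a median of 0.47 (adjusted p = 0.0428, and adjusted p = 0.784 with an estimated correlation). The glycogen synthase GSY1 (1.79 ± 0.13), the trehalose synthases TPS1 (1.28) and TSL1 (0.92) and UGP1 (0.77) were higher.

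The PAU family of cell wall mannoproteins, whose copies are so alike that probes can share signal, was higher in 21 of 24 genes, with a median of 0.48 (adjusted p = 1.19e-05, and adjusted p = 0.754 with an estimated correlation). PAU10 was at 0.53 and PAU6 at 0.52. Cell cycle and replication genes were higher in 17 of 30 cases and lower in 3 (CLN3, PRI1 and MCM3), with a median of 0.28 (adjusted p = 7.68e-04, and adjusted p = 0.771 with an estimated correlation). The mitotic cyclin CLB1 (1.54 ± 0.07) and the late-mitosis factors SWI5 (1.41) and CDC5 (0.96) stood out. Fatty acid synthesis genes were higher in 8 of 13 cases and lower in 2 (TSC13 and FAA4), with a median of 0.32 (adjusted p = 0.0428, and adjusted p = 0.169 with an estimated correlation), such as PHS1 (0.87) and ELO1 (0.72). Of 9 histone genes 5 were higher (HTA1, HTB1, HHF1, HHF2 and HTZ1), with a median of 0.34 (adjusted p = 0.0428, and adjusted p = 0.776 with an estimated correlation).

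Nitrogen genes of the panel went both ways or were not called. The general amino acid permease GAP1 (-0.20 ± 0.12, adjusted p = 0.17), the ammonium permease MEP2 (-0.04 ± 0.07), BAT2 (-0.16) and LYS20 (-0.11) were not called. GAP1 and BAT2 were called when these groups were fitted alone (adjusted p = 0.014 and 0.0425), without ammonium sample 2 (0.0197 and 0.0327) and without 3 samples that stood apart from their groups, batch 1, ammonium 2 and valine 3 (0.0059 and 0.00501), a setting chosen after the data were seen, and BAT2 with array weights (0.0476). The repressor DAL80 was 0.26 ± 0.10 higher (adjusted p = 0.0428), a call that ended without batch sample 2, 3 or 4, no-addition sample 1, 2 or 3 or valine sample 1 (adjusted p = 0.0537 to 0.118), with slide (0.129) or replicate number (0.0661) as a block and after renewed quantile normalization (0.051). GDH1, the anabolic glutamate dehydrogenase, was higher by 0.34 ± 0.10 and BAT1 by 0.39, while GLN1 (-0.39), ILV5 of valine synthesis (-1.20 ± 0.22) and CYC1 (-0.70) were lower. ARO10 of the Ehrlich pathway (0.78) and the glucose transporter HXT6 (0.58) were higher. PDC1 at 0.07, HXT1 at 0.01 and ATF1 at 0.00 were not called.

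In all, limma called 3582 of 6248 genes, 1896 higher in the third stage and 1686 lower, of which 90 and 183 changed at least 2-fold. The groups did not overlap in 52.4% of genes, against 2.86% by chance. With slide as a block 3395 genes and 12 lists were called, within slide 1 1682 genes and within slide 2 2387. The median of ribosome biogenesis was -1.05 with the block and -1.06 within either slide, that of ribosomal proteins -0.62, -0.60 and -0.59, and that of the proteasome 0.53, 0.47 and 0.56, and all 13 lists kept the sign of their median. Adjusted over the list alone, counts of the lists past the threshold were equal except for 22 higher PAU genes, 30 proteasome genes, 18 cell cycle genes and 3 iron genes. In the lists for aromatic amino acids and histidine, sulfur amino acids, one-carbon metabolism, glycerol, poor nitrogen sources and haploid mating, which did not pass, the median, the mean and the test differed in sign. Trehalose and glycogen lost its call with slide as a block (adjusted p = 0.0507), without batch sample 1 (0.0748), no-addition sample 3 (0.0661) or valine sample 3 (0.0508), and fatty acid synthesis without batch sample 1 (0.0997) or no-addition sample 4 (0.0534). Histones lost theirs without batch sample 3 (0.0686) or no-addition sample 4 (0.0528) and after removal of the trend with gene length (0.561). That removal also ended the call of HHF1 (0.0542). With the dimmest genes left out, trehalose and glycogen, fatty acid synthesis and histones all lost their calls (camera adjusted p = 0.0792 each). Fatty acid synthesis also lost its call without the 3 samples that stood apart (0.13).

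**Figure D1:**
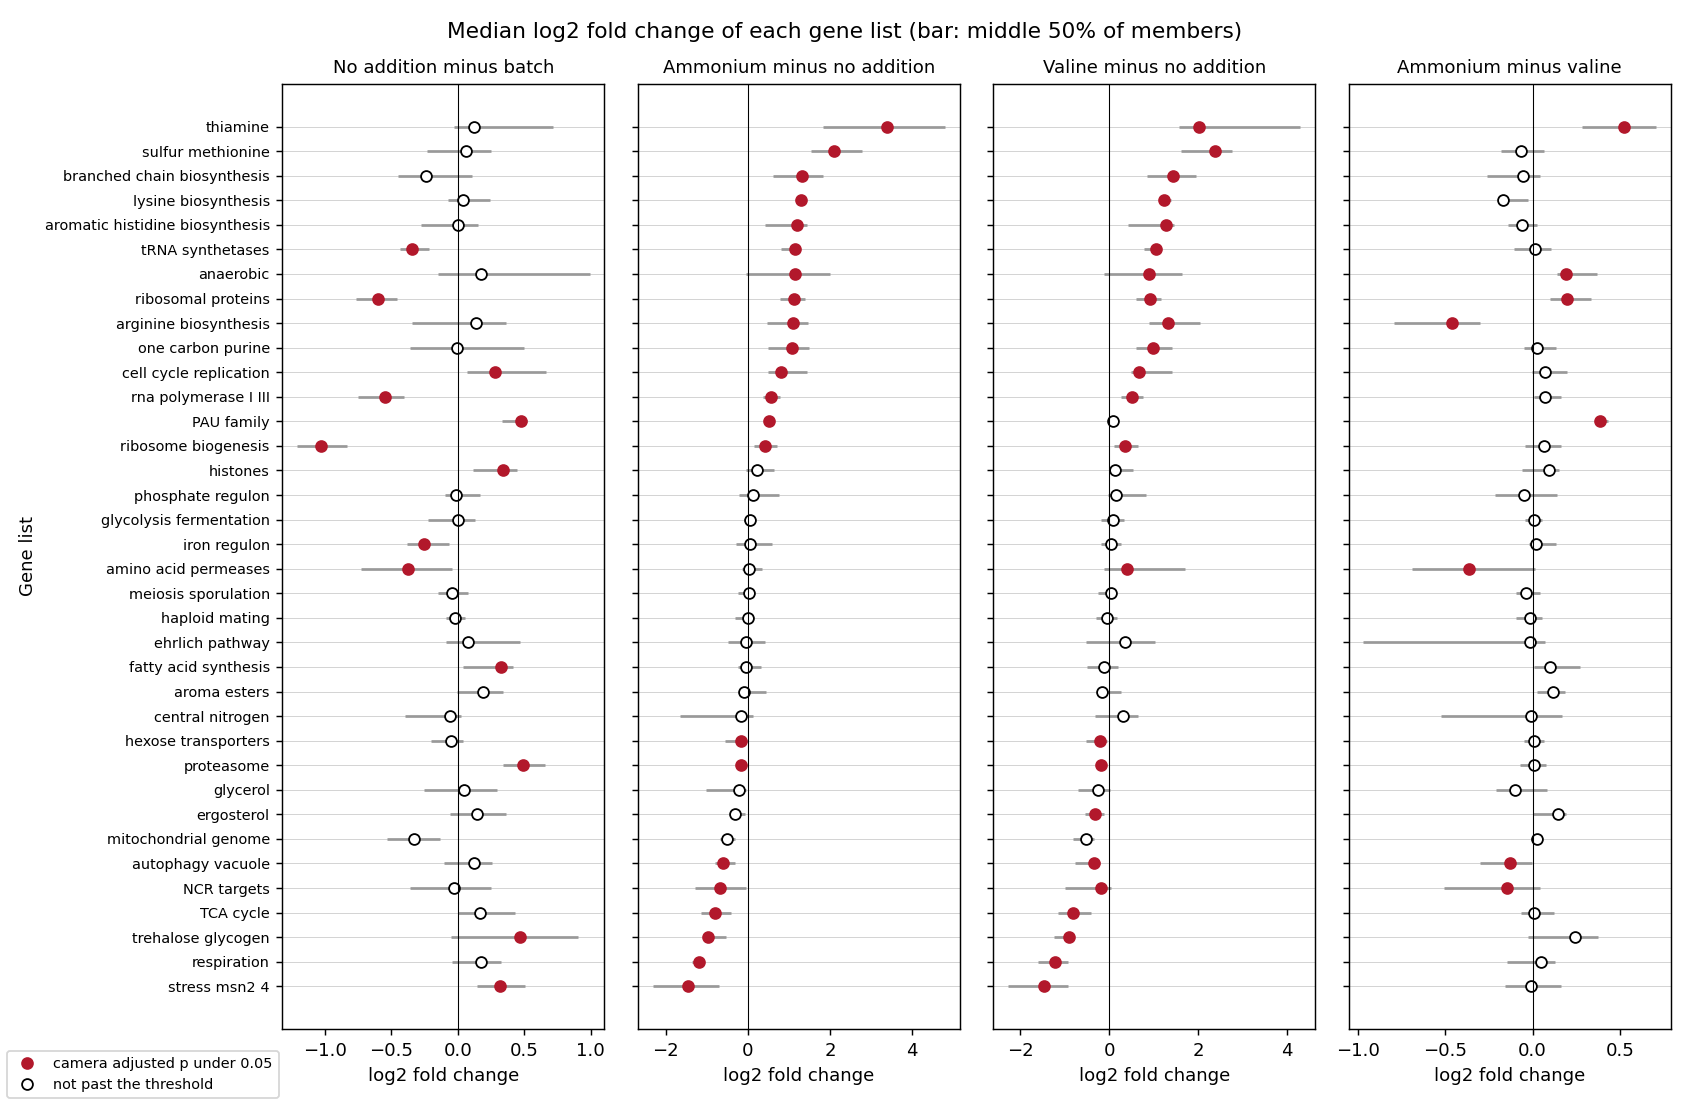
Median log2 fold change of each of the 36 gene lists in the 4 comparisons, with a bar over the middle 50% of members and filled points for lists past the camera threshold at the preset correlation. Ribosome biogenesis lies at -1.03 between the third stage and batch and at 0.41 with ammonium, and the stress list at -1.46 with ammonium and -1.47 with valine.

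The second comparison asked what ammonium did to the resting cells of the third stage. Thiamine genes rose most: THI11, one of a set of near-identical genes for the thiamine pyrimidine precursor, went from 7.59 without addition (n = 4) to 13.80 with ammonium (n = 3), a log2 fold change of 6.20 ± 0.51 (SE). Its copies THI13 (6.13 ± 0.40), THI5 (6.06 ± 0.49) and THI12 (6.02 ± 0.46) share most of their sequence, so these may be 1 signal, and THI22 rose by 5.33 ± 0.32. No-addition sample 4 lay far above the other 3 samples in these genes, and without it the log2 fold changes were 6.91 for THI11, 6.68 for THI13, 6.72 for THI5, 6.66 for THI12 and 5.76 for THI22. The hexose transporter HXT5, typical of slow growth, fell from 12.47 to 6.84, a change of -5.63 ± 0.15. The stress genes DDR2 (-4.91 ± 0.39) and SIP18 (-4.78 ± 0.23), the phosphogluconate dehydrogenase GND2 (-4.50 ± 0.11) and SPG4 (-4.27 ± 0.14) fell as well.

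Pathways that make vitamins and amino acids rose. All thiamine and vitamin B6 genes but the regulator PDC2 rose, 21 of 22, with a median of 3.39 (camera adjusted p = 2.28e-12, and adjusted p = 0.149 with an estimated correlation), or 3.48 without no-addition sample 4; SNZ2 (3.33) and THI6 (2.09 ± 0.06) were examples. All 24 genes of sulfur amino acid synthesis rose, with a median of 2.09 (adjusted p = 4.93e-12, and adjusted p = 0.159 with an estimated correlation), among them MET10 (3.05 ± 0.13), CYS3 (3.01 ± 0.11) and the sulfate permease SUL2 (2.88 ± 0.14). Branched-chain amino acid synthesis rose in 11 of 12 genes, all but LEU1, with a median of 1.32 (adjusted p = 5.52e-06, and adjusted p = 0.149 with an estimated correlation), with ILV3 at 2.36, ILV5 at 1.86 and BAT1 at 1.83. For lysine 8 of 9 genes rose and LYS5 fell, with a median of 1.29 (adjusted p = 0.0011, and adjusted p = 0.264 with an estimated correlation). For arginine 6 of 8 rose, such as ARG4 at 1.65, and CPA1 fell, with a median of 1.11 (adjusted p = 0.00929, and adjusted p = 0.313 with an estimated correlation). Aromatic amino acid and histidine synthesis rose in 16 of 19 genes and fell in TRP1, with a median of 1.19 (adjusted p = 3.75e-07, and adjusted p = 0.104 with an estimated correlation). HIS1 (1.92) and ARO1 (1.76) were among them. In one-carbon and purine metabolism 15 of 19 genes rose and ADE16 fell, with a median of 1.08 (adjusted p = 4.12e-06, and adjusted p = 0.104 with an estimated correlation), including SHM2 (1.47).

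Genes of protein synthesis and of the cell cycle rose. Ribosomal proteins rose in 133 of 135 genes and fell in 0, with a median of 1.12 (adjusted p = 1.72e-30, and adjusted p = 0.104 with an estimated correlation), among them RPS22A (2.00 ± 0.09) and RPS4A (1.31 ± 0.05). Ribosome biogenesis rose in 70 of 104 genes and fell in 5 (NOP16, FAF1, LTV1, RIO1 and RMP1), with a median of 0.41 (adjusted p = 1.35e-07, and adjusted p = 0.418 with an estimated correlation). RNA polymerases I and III rose in 21 of 24 subunits and fell in RPC34 and RPC37, with a median of 0.58 (adjusted p = 6.22e-06, and adjusted p = 0.104 with an estimated correlation). Of 18 tRNA synthetases 17 rose, with a median of 1.15 (adjusted p = 3.00e-08, and adjusted p = 0.149 with an estimated correlation), such as FRS1 (1.54). Cell cycle and replication genes rose in 28 of 30 cases and fell in 0, with a median of 0.81 (adjusted p = 1.25e-09, and adjusted p = 0.181 with an estimated correlation). The ribonucleotide reductase RNR1 (2.64 ± 0.08) and CLB1 (1.74 ± 0.08) were the clearest of them.

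Anaerobic genes and the PAU family rose as well. Genes of the anaerobic list rose in 15 of 21 cases and fell in 4 (COX5B, CYC7, OLE1 and ROX1, a repressor of anaerobic genes). The list median was 1.14 (adjusted p = 0.00234, and adjusted p = 0.264 with an estimated correlation), with TIR2 at 2.86 ± 0.10 and the sterol importer AUS1 at 2.17 ± 0.11. The PAU family rose in 23 of 24 genes, with a median of 0.51 (adjusted p = 1.17e-05, and adjusted p = 0.387 with an estimated correlation), such as PAU11 (0.86).

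Stress, respiration and reserve genes fell. Stress genes fell in 34 of 36 cases and rose in 0, with a median of -1.46 (adjusted p = 2.75e-11, and adjusted p = 0.264 with an estimated correlation), including GRE1 (-3.77 ± 0.12) and HSP12 (-2.90 ± 0.09). All 35 respiration genes fell, with a median of -1.18 (adjusted p = 7.27e-13, and adjusted p = 0.0764 with an estimated correlation), such as COX5A (-1.93 ± 0.08), COX4 (-1.68) and CYC1 (-1.23). The TCA cycle fell in 18 of 23 genes, including MDH2 (-2.33) and SDH2 (-1.36), and rose in 4 (CIT2, IDP1, PYC1 and PYC2), with a median of -0.80 (adjusted p = 1.39e-04, and adjusted p = 0.104 with an estimated correlation). CIT2 is the peroxisomal citrate synthase, and PYC1 and PYC2 are pyruvate carboxylases. Trehalose and glycogen genes fell in 15 of 17 cases and GSY1 rose, with a median of -0.97 (adjusted p = 9.62e-04, and adjusted p = 0.434 with an estimated correlation), with GLG2 at -1.25 and TSL1 at -0.62. Ammonium sample 2 hardly fell in this list: its median deviation from the mean of all samples was 0.23, near the no-addition samples (0.38 to 0.55), against -0.57 and -0.51 in ammonium samples 1 and 3. TSL1 stood at 11.40 in it and at 10.54 and 10.56 in these samples, and without it the change in TSL1 was -0.90 and the list median -1.14. Autophagy genes fell in 19 of 24 cases and rose in 0, with a median of -0.60 (adjusted p = 4.10e-05, and adjusted p = 0.104 with an estimated correlation), among them ATG8 (-1.54 ± 0.11) and ATG2 (-1.07). The proteasome fell in 16 of 33 genes, with a median of -0.17 (adjusted p = 0.0179, and adjusted p = 0.418 with an estimated correlation), and its activator RPN4 fell by 0.99. Hexose transporters and their sensors fell in 10 of 20 genes and HXT15 rose, with a median of -0.17 (adjusted p = 0.0179, and adjusted p = 0.264 with an estimated correlation), with HXT6 at -1.62 and HXT1 at -0.99.

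Genes for the use of poor nitrogen sources fell in 21 of 34 cases and rose in 3 (MEP3, CPS1 and RSN1), with a median of -0.67 (adjusted p = 4.44e-04, and adjusted p = 0.374 with an estimated correlation). Examples were LEE1 (-2.09), the allantoinase DAL1 (-2.02 ± 0.13) and PUT2 of proline use (-1.62 ± 0.06). GAP1 fell by 0.75, MEP2 by 0.62 and DAL80 by 1.00 on the log2 scale. GDH1 rose by 2.22 ± 0.10 and LYS20 by 1.39, THI4 rose by 3.74, and ARO10 fell by 0.46. With ammonium THI4 lay between 15.73 and 15.85, near the array maxima of 15.82 to 15.96, so its rise may be understated. BAT2 (0.17), GLN1 (0.12) and PDC1 (-0.05) were not called, though GLN1 was without the 3 samples that stood apart (0.18, adjusted p = 0.0359). ATF1 (-0.15) and HSP26 (-0.42) were called at adjusted p = 0.0305 each. ATF1 lost its call without no-addition sample 2 or 3 or ammonium sample 1 or 2 (adjusted p = 0.051 to 0.118), without the 3 samples that stood apart (0.0631) and with the slide 2 array of ammonium sample 3 (0.134), and HSP26 without no-addition sample 1 or 3 or ammonium sample 1 or 3 (0.0729 to 0.13).

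Between ammonium and no addition 4224 genes were called, 2008 higher with ammonium and 2216 lower, of which 430 and 349 differed at least 2-fold. Groups did not overlap in 71.5% of genes, against 5.71% by chance. The slide block left 4213 called genes, slide 1 alone 2477 and slide 2 alone as many as all samples, 4016 of them the same genes in the same direction. With 23 lists called under the block, all 22 lists above kept the sign of their median in each setting: the stress list was at -1.46, -1.54 and -1.45, ribosomal proteins at 1.12, 1.20 and 1.09, and sulfur amino acids at 2.09, 2.33 and 2.07. The list that the block added was ergosterol (median -0.33, camera adjusted p = 0.0463). Adjusted over the list alone, counts of the lists past the threshold were equal except for branched-chain synthesis (12 higher), one-carbon metabolism (16 higher) and hexose transporters (9 lower, 0 higher). In the lists for aroma esters, fatty acid synthesis, meiosis and the Ehrlich pathway, which did not pass, the median, the mean and the test differed in sign.

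**Figure D2:**
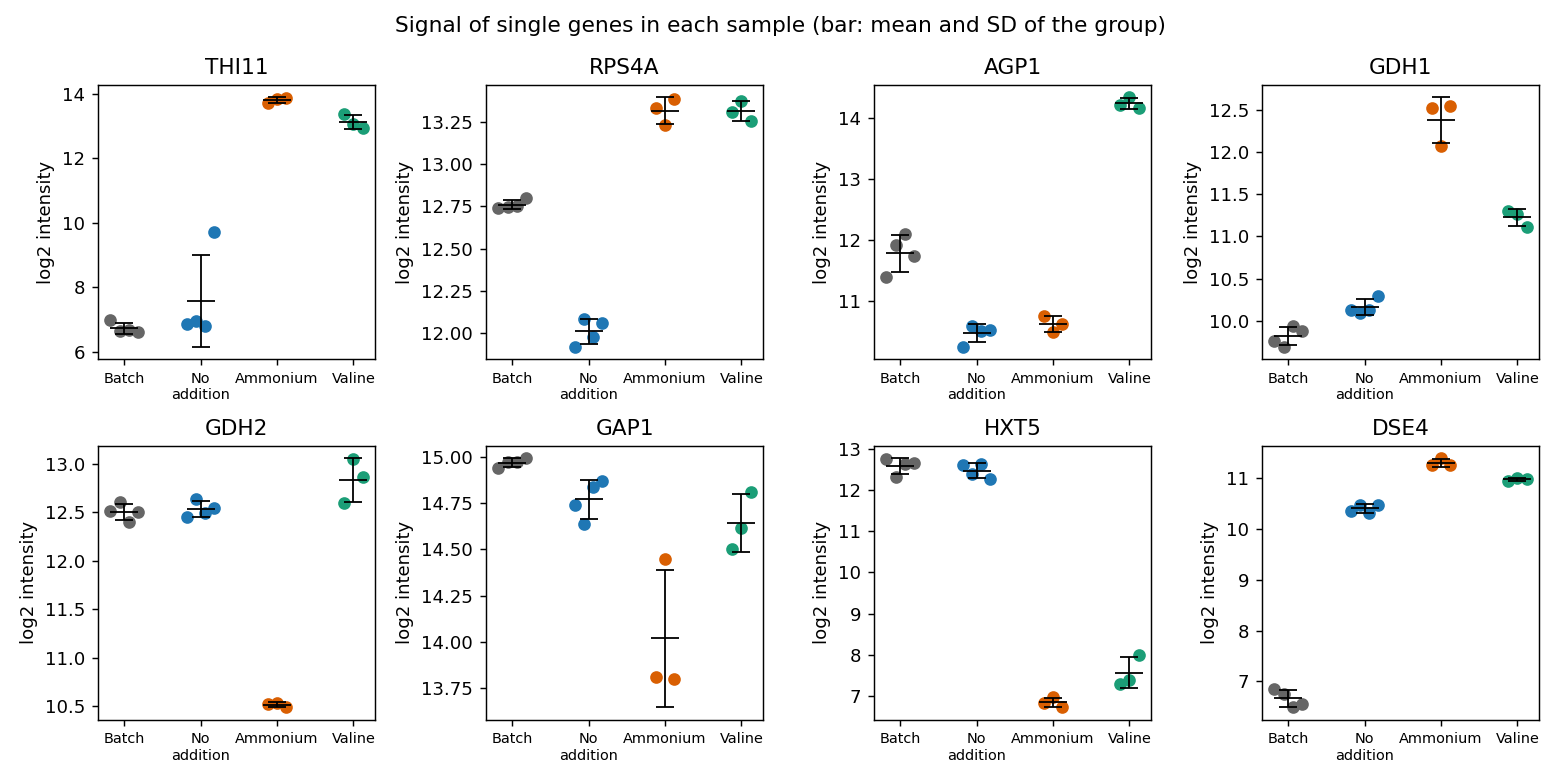
Log2 intensity of 8 genes in each sample of the 4 groups, with a line for the group mean and bars for its SD. AGP1 stands at 14.23 with valine and 10.63 with ammonium, GDH2 at 12.83 and 10.52, and the points of no-addition sample 4 and the other no-addition samples part in THI11.

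The third comparison asked the same of valine, an amino acid that serves as the sole added nitrogen source. Thiamine genes again rose most, with THI11 at 5.53 ± 0.51 (SE, 3 valine against 4 no-addition samples), THI5 at 5.20 ± 0.49, THI12 at 5.13 ± 0.46, THI13 at 5.02 ± 0.40 and THI22 at 5.02 ± 0.32. Without no-addition sample 4 these log2 fold changes were 6.24, 5.86, 5.76, 5.57 and 5.45. Some permeases for amino acids rose strongly: AGP1 went from 10.48 to 14.23 (3.75 ± 0.13), DIP5 rose by 3.53 ± 0.15 and the branched-chain permease BAP2 by 2.48 ± 0.11. HXT5 fell from 12.47 to 7.56 (-4.91 ± 0.15), and DDR2 (-4.56 ± 0.39), SIP18 (-4.50 ± 0.23), the allantoin permease DAL4 (-4.39 ± 0.26) and the thiolase POT1 (-4.27 ± 0.11) fell with it.

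Synthesis of vitamins and amino acids rose. The thiamine list rose in 21 of 22 genes, all but PDC2, with a median of 2.03 (camera adjusted p = 6.64e-11, and adjusted p = 0.141 with an estimated correlation), or 2.10 without no-addition sample 4. All 24 sulfur amino acid genes rose, with a median of 2.39 (adjusted p = 1.72e-12, and adjusted p = 0.141 with an estimated correlation), such as MET10 (3.18 ± 0.13) and STR3 (2.76 ± 0.11). All 12 branched-chain synthesis genes rose in the presence of added valine, with a median of 1.44 (adjusted p = 1.69e-06, and adjusted p = 0.141 with an estimated correlation), with ILV3 at 2.28, BAT1 from 12.17 to 14.30, ILV5 at 1.89 and LEU4 at 1.86. Lysine genes rose in 8 of 9 cases and LYS5 fell, with a median of 1.23 (adjusted p = 5.49e-04, and adjusted p = 0.215 with an estimated correlation). Arginine genes rose in 7 of 8 cases, with a median of 1.33 (adjusted p = 6.13e-04, and adjusted p = 0.203 with an estimated correlation), with ARG1 at 2.22 and ARG4 at 2.00. Of 19 aromatic and histidine genes 18 rose and TRP1 fell, with a median of 1.27 (adjusted p = 1.14e-07, and adjusted p = 0.117 with an estimated correlation). One-carbon and purine genes rose in 16 of 19 cases and ADE16 fell, with a median of 1.00 (adjusted p = 1.17e-06, and adjusted p = 0.117 with an estimated correlation). Amino acid permeases rose in 11 of 20 cases and fell in 4 (AGP2, TAT1, PTR2 and ALP1), with a median of 0.40 (adjusted p = 0.0275, and adjusted p = 0.337 with an estimated correlation), a call that ended after removal of the trend with gene length (adjusted p = 0.055).

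Translation and division genes rose here too. Ribosomal proteins rose in 129 of 135 genes and fell in 1, RPS30B, with a median of 0.92 (adjusted p = 4.72e-25, and adjusted p = 0.141 with an estimated correlation), with RPS4A at 1.30 ± 0.05 and RPS2 at 1.24. Ribosome biogenesis rose in 64 of 104 genes and fell in 7, with a median of 0.36 (adjusted p = 5.59e-06, and adjusted p = 0.503 with an estimated correlation). RNA polymerases I and III rose in 21 of 24 subunits and RPC34 fell, with a median of 0.52 (adjusted p = 1.85e-05, and adjusted p = 0.141 with an estimated correlation). Of 18 tRNA synthetases 17 rose, with a median of 1.06 (adjusted p = 2.16e-08, and adjusted p = 0.141 with an estimated correlation). Cell cycle and replication genes rose in 28 of 30 cases and CLN3 fell, with a median of 0.68 (adjusted p = 2.16e-08, and adjusted p = 0.203 with an estimated correlation), with RNR1 at 2.53 and CLB1 at 1.73. The anaerobic list rose in 15 of 21 genes and fell in 4 (COX5B, CYC7, OLE1 and the repressor ROX1). Its median was 0.89 (adjusted p = 0.0108, and adjusted p = 0.335 with an estimated correlation), with TIR2 at 2.33. The PAU family was not called as a list (median 0.10, adjusted p = 0.245), with PAU7, PAU8, PAU11 and PAU12 higher and PAU23 lower, but it passed once the trend with gene length was removed (median 0.29, adjusted p = 0.00198).

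Stress and respiration fell. Of 36 stress genes 35 fell and HSP82 rose, with a median of -1.47 (adjusted p = 6.96e-12, and adjusted p = 0.227 with an estimated correlation), with SSA3 at -3.41 and HSP12 at -2.27. All 35 respiration genes fell, with a median of -1.23 (adjusted p = 4.88e-13, and adjusted p = 0.073 with an estimated correlation), with COX5A at -1.86 and CYC1 at -1.77. The TCA cycle fell in 18 of 23 genes and rose in 5 (CIT2, CIT3, IDP1, PYC1 and PYC2), with a median of -0.81 (adjusted p = 1.18e-04, and adjusted p = 0.117 with an estimated correlation). Trehalose and glycogen genes fell in 16 of 17 cases, with a median of -0.91 (adjusted p = 6.49e-05, and adjusted p = 0.354 with an estimated correlation), such as the glycogen phosphorylase GPH1 (-1.80 ± 0.16). Autophagy genes fell in 16 of 24 cases and ATG22 rose, with a median of -0.34 (adjusted p = 0.00155, and adjusted p = 0.141 with an estimated correlation). The proteasome fell in 20 of 33 genes and RPN1 rose, with a median of -0.18 (adjusted p = 0.0244, and adjusted p = 0.453 with an estimated correlation). Hexose transporters fell in 9 of 20 cases and HXT8 rose, with a median of -0.20 (adjusted p = 0.0182, and adjusted p = 0.215 with an estimated correlation). Ergosterol genes fell in 16 of 25 cases and rose in ERG4 and NCP1, with a median of -0.33 (adjusted p = 0.014, and adjusted p = 0.571 with an estimated correlation), with HMG1 of the mevalonate pathway at -1.26 ± 0.12. That fall was not particular to valine: with ammonium the list median was -0.32, though the list was not called. It passed there with slide as a block (adjusted p = 0.0463) and after removal of the trend with gene length (0.0403).

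Genes for poor nitrogen sources parted: 16 of 34 fell and 5 rose (CPS1, OPT2, VBA1, RSN1 and NIT1), with a median of -0.18 (adjusted p = 0.0377, and adjusted p = 0.578 with an estimated correlation). The list lost its call without batch sample 1 (adjusted p = 0.0589) and without the dimmest 25% of genes (0.102). DAL4 fell most and LEE1 (-1.59) and PUT2 (-1.35) fell, as did MEP2 (-0.68) and DAL80 (-0.66), whereas GAP1 at -0.13 ± 0.13 was not called (adjusted p = 0.389) unless the 3 samples that stood apart were left out (-0.21, 0.01). BAT2, which starts the breakdown of branched-chain amino acids, rose by 1.90 ± 0.11, GDH1 by 1.07 ± 0.10, GLN1 by 0.64, LYS20 by 1.17 and THI4 by 3.83. In valine samples 1 and 3 THI4 equalled the array maximum (15.90 and 15.92), so its rise may be understated. ARO10 (-0.78), HSP26 (-0.96), TSL1 (-0.86), HXT6 (-1.72) and HXT1 (-0.50) fell. PDC1 at -0.12 was not called. ATF1 (-0.15, adjusted p = 0.034) lost its call without no-addition sample 2 or 3 or valine sample 2 or 3 (0.0554 to 0.119), without the 3 samples that stood apart (0.115), with slide as a block (0.0576) and with the slide 2 array of ammonium sample 3 (0.0595).

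Between valine and no addition 4242 genes were called, 2019 higher with valine and 2223 lower, of which 407 and 358 differed at least 2-fold. Groups did not overlap in 69.6% of genes, against 5.71% by chance. With slide as a block 4146 genes and 23 lists were called, within slide 1 2749 genes and within slide 2 3488. All 23 lists kept the sign of their median in each setting, with the stress list at -1.49, -1.45 and -1.44, ribosomal proteins at 0.93, 0.90 and 1.02, and amino acid permeases at 0.41, 0.50 and 0.35. Adjusted over the list alone, every list past the threshold had equal counts. In the aroma ester list, which did not pass, the median (-0.15) lay below 0 while the mean and the test lay above, and in the fatty acid synthesis and meiosis lists the mean opposed the median and the test.

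**Figure D3:**
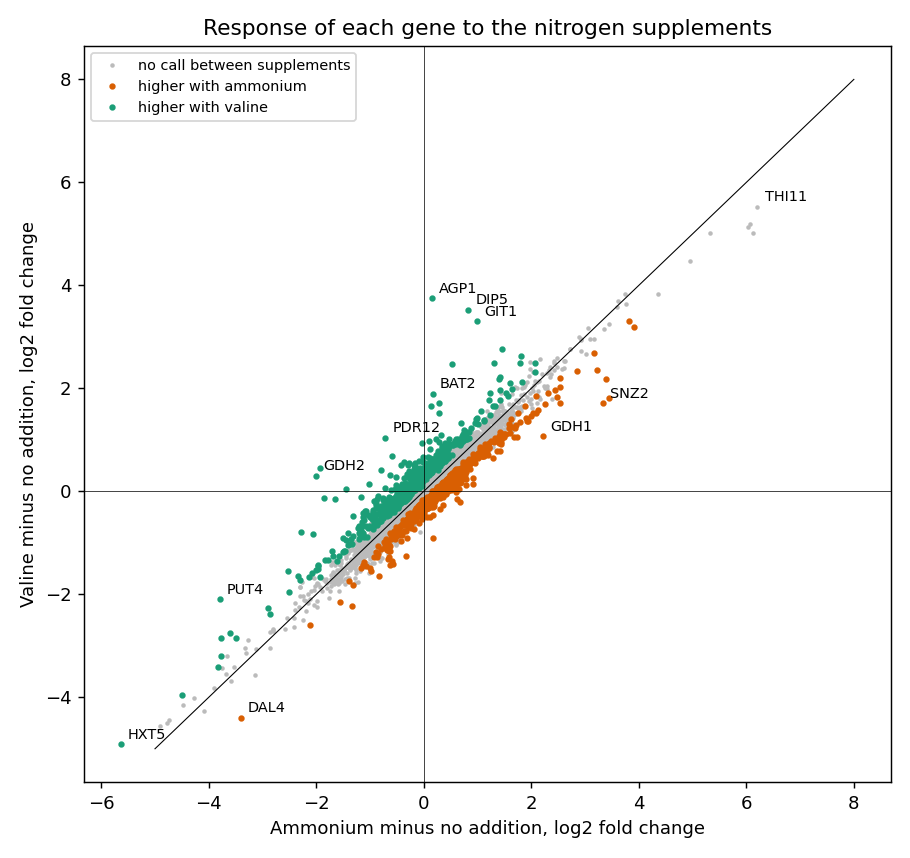
Log2 fold change of each of 6248 genes with valine (vertical axis) against that with ammonium (horizontal axis), both over no addition, coloured by the call between the supplements, with the line of equal change. Most genes lie along the line, and AGP1 (0.15 with ammonium, 3.75 with valine) lies far above it.

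The responses to both supplements were set side by side to see how far they were shared. In the same direction 3637 genes were called with both, 1724 higher and 1913 lower, where independent lists of these sizes would share 649 and 788. Both comparisons use the same no-addition samples, which alone makes fold changes correlate. Simulated groups without change had a mean correlation of 0.43 across genes, against 0.95 observed, and a mean covariance of 0.00341, against 0.511 observed. With separate pairs of no-addition samples for each supplement the correlation was 0.93 to 0.95, the covariance 0.506 to 0.512 and the number of shared calls 3206 to 3284. Genes are not independent replicates, so no p is given for these correlations across genes. The number of shared calls was 3599 with slide as a block. Opposite calls were found for 37 genes, all of which were also called between the supplements. Opposite calls against the same controls in 1 fit nearly ensure this, so it is no separate support. The catabolic glutamate dehydrogenase GDH2 (-2.01 with ammonium, 0.30 with valine), the weak acid exporter PDR12 (-0.72, 1.04), the peptide transporter OPT2 (-0.79, 0.42) and VBA1 (-0.63, 0.32) were among them. Calls with ammonium alone numbered 550, of which 212 were called between supplements, and calls with valine alone 568, of which 160 were.

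The last comparison set ammonium directly against valine at equal added nitrogen. The largest difference was in the amino acid permease AGP1, at 10.63 with ammonium against 14.23 with valine (log2 fold change -3.60 ± 0.14 SE, n = 3 and 3, adjusted p = 1.37e-09 by limma). DIP5 (-2.71 ± 0.16), GDH2 (-2.31 ± 0.09), the glycerophosphoinositol permease GIT1 (-2.31 ± 0.22) and BAP2 (-1.95 ± 0.12) were lower as well, and so was BAT2 (-1.73 ± 0.11). Vitamin B6 genes were higher with ammonium, SNZ2 by 1.62 ± 0.11 and SNZ3, nearly identical to it, by 1.62 ± 0.12. GDH1 was higher by 1.15 ± 0.11, the cell wall gene HPF1 by 0.93 ± 0.16 and DAL4 by 0.99 ± 0.28 (adjusted p = 0.0291). Valine sample 3 was low in HPF1, at 10.31 against 11.06 and 11.07 in samples 1 and 2. Without it HPF1 was higher by 0.68 and still called (adjusted p = 0.00136). DAL4 lost its call without valine sample 1 (adjusted p = 0.0798), without valine sample 2 (0.0977), with slide as a block (0.0699) and with these groups fitted alone (0.121). Its value rested on ammonium sample 2, at 10.23 against 8.72 and 8.73 in samples 1 and 3, and was 0.48 without it, where the call held (adjusted p = 0.0051).

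Thiamine genes and the PAU family were higher with ammonium. The thiamine list was higher in 12 of 22 genes and lower in 0, with a median of 0.52 (camera adjusted p = 2.15e-09, and adjusted p = 0.433 with an estimated correlation), with SNO2 at 0.67, while THI4 at -0.09 was not called. THI4 lay between 15.73 and 15.92 with both supplements, at or near the array maxima of 15.82 to 15.96, so a difference could be hidden. The PAU family was higher in 19 of 24 genes, with a median of 0.39 (adjusted p = 9.24e-13, and adjusted p = 0.433 with an estimated correlation), among them PAU5 (0.77 ± 0.08), PAU17 (0.61) and PAU7 (0.52). Ribosomal proteins were higher in 45 of 135 genes and lower in 1, RPP1, an RNase P subunit that the name rule of the list takes in, with a median of 0.20 (adjusted p = 1.97e-12, and adjusted p = 0.449 with an estimated correlation), with RPL22B at 0.66 and RPS22A at 0.54. In the anaerobic list 3 of 21 genes were higher (TIR2, DAN4 and ROX1), with a median of 0.19 (adjusted p = 0.0159, and adjusted p = 0.472 with an estimated correlation). ROX1 represses anaerobic genes and so is no like member of the list. That list call ended with slide as a block (adjusted p = 0.0635). TIR2 was at 0.53. DAN4 (0.32) lost its call without valine sample 2 (0.0655), and ROX1 (0.76) lost it with slide as a block (0.0531) and without ammonium sample 1 or 2 or valine sample 1 or 2 (0.0531 to 0.0657) and with the slide 1 array of ammonium sample 3 (0.0595).

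Amino acid uptake, arginine synthesis and the use of poor nitrogen sources were lower with ammonium. Of 20 amino acid permeases 10 were lower and HIP1 was higher, with a median of -0.36 (adjusted p = 3.28e-07, and adjusted p = 0.268 with an estimated correlation). Arginine synthesis was lower in 6 of 8 genes, with a median of -0.46 (adjusted p = 2.79e-04, and adjusted p = 0.433 with an estimated correlation), with ARG1 at -0.81 and ARG3 at -0.78. ARG3 lost its call when these groups were fitted alone (adjusted p = 0.0652). Ammonium sample 2 lay low in it, at 10.59 against 11.50 in samples 1 and 3, and without that sample ARG3 was at -0.48 and CPA1 at -0.39 instead of -0.54. Among genes for poor nitrogen sources 11 of 34 were lower and 5 higher (DAL2, DAL3, DAL4, DAL7 and CAR1), with a median of -0.15 (adjusted p = 0.00304, and adjusted p = 0.656 with an estimated correlation). OPT2 (-1.21), AMD2 (-1.15) and VBA1 (-0.95) were lower, and the higher ones belong to allantoin and arginine use. Autophagy genes were lower in 6 of 24 cases, with a median of -0.13 (adjusted p = 0.0176, and adjusted p = 0.448 with an estimated correlation), such as YSP3 (-0.65) and ATG7 (-0.49), and that list lost its call without ammonium sample 1 (0.0536) or ammonium sample 3 (0.0666).

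In the panel GAP1 (-0.62 ± 0.14), GLN1 (-0.52), HXT1 (-0.49) and HSP12 (-0.64) were lower with ammonium. The call of GAP1 ended when these groups were fitted alone (adjusted p = 0.0577). BAT1 (-0.29) lost its call without ammonium sample 2 (0.062) or valine sample 1 (0.053), without the 3 samples that stood apart (0.0623) and with the slide 2 array of ammonium sample 3 (0.149). HSP26 was higher by 0.54 (adjusted p = 0.0446), and that call ended with slide (0.0906) or replicate number (0.0848) as a block and when any of 9 samples was left out (0.0526 to 0.168), which were batch 2 and 4, no-addition 1, 2 and 4, ammonium 2 and 3 and valine 1 and 2. ARO10 (0.31), CYC1 (0.53), DAL80 (-0.34), LYS20 (0.21), TSL1 (0.24), HXT6 (0.10), PDC1 (0.07), MEP2 (0.05), ILV5 (-0.03) and ATF1 (0.00) were not called. Other settings called some of these genes. ARO10 was called with slide as a block (0.39, adjusted p = 0.0267), within slide 2 (0.61, 0.00904), with array weights (0.0209) and without batch sample 1 (0.0446) or valine sample 1 (0.00764). Valine sample 3 was lowest in ARO10, at 6.92 against 7.49 and 7.24, and without it the difference was 0.16 (0.182). CYC1 was called without batch sample 1 (0.0176) or ammonium sample 3 (0.0208). Without ammonium sample 2 LYS20 was at 0.47 (0.00508) and DAL80 at -0.49 (0.00888), and both were also called with array weights (0.00766 and 6.33e-04) and without the 3 samples that stood apart (0.00384 and 0.00104), DAL80 also without batch sample 1 (0.0281).

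Between the supplements limma called 1023 genes, 474 higher with ammonium and 549 lower, of which 5 (SNZ2, SNZ3, GDH1 and 2 probes without a gene symbol) and 23 differed at least 2-fold. Groups did not overlap in 34.3% of genes, against 10% by chance for 3 samples against 3. The count rested on single samples: 664 genes were called without valine sample 1 and 501 without valine sample 2, and 13 lists without ammonium sample 2. Of the lists gained, cell cycle (median 0.20, camera adjusted p = 5.58e-06), ribosome biogenesis (0.12, 0.00184) and RNA polymerases I and III (0.13, 0.0443) were higher with ammonium. Stress genes (-0.16, 0.00247) and the Ehrlich pathway (-0.04, 0.0187) were lower. These lists also passed without the 3 samples that stood apart. With slide as a block 697 genes and 7 lists were called, within slide 1 38 genes and within slide 2 228. All 8 lists kept the sign of their median in these settings, with the PAU family at 0.35, 0.34 and 0.33, amino acid permeases at -0.34, -0.24 and -0.33, and thiamine genes at 0.51, 0.51 and 0.65. Adjusted over the list alone, 23 PAU genes, 14 thiamine genes, 60 ribosomal protein genes and 5 anaerobic genes were higher, 14 genes for poor nitrogen sources were lower with 6 higher, 7 autophagy genes were lower, and the other lists past the threshold had equal counts. In the lists for hexose transporters, the TCA cycle, respiration, the proteasome and tRNA synthetases, which did not pass, the median, the mean and the test differed in sign.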

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

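Of the tests below, the comparison of slides for the thiamine genes was chosen after the result was seen. A sample was singled out where its gap to the nearest sample of its group was too large a part of the range of 4 samples. Over 414 such tests of named genes and lists this happened 24 times, where chance alone gives about 1 in 20 groups, or 21, so single cases carry little weight. Values are differences on the log2 scale between the sample and the others of its group.

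In no-addition sample 4 the thiamine genes stood high together: THI11 by 2.84, THI5 by 2.65, THI12 by 2.53, THI13 by 2.20 and THI22 by 1.74, with the thiamine list at 0.508. In the same sample SNZ2 was high by 0.345, MET10 by 0.449 and the sulfur amino acid list by 0.202.

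Slide is argued against as the source of the thiamine excess, because no-addition samples 2 and 3 on the same slide differed from sample 1 by -0.0332 in THI5, THI11, THI12 and THI13, where sample 4 exceeded the others by a median of 2.59. Admixture of RNA from cells with added nitrogen is a candidate explanation that stays open: a share of 4.51% ammonium RNA (SE 0.237, 52 other genes at least 4-fold higher with both supplements) lies close to the 4.91% that fits the 4 thiamine genes, and 100% of those 52 genes were higher in sample 4 than in the other samples. With the valine profile the shares were 4.77% and 8.64%, and the 10 genes specific to valine gave a median of 0.567%, against 3.17% over 5 genes specific to ammonium. In no-addition samples 1, 2 and 3 the fitted share of ammonium RNA was -1.55%, -1.12% and -1.83%. Each of these was taken against the other no-addition samples, with sample 4 among them. Shares below 0 thus follow from the excess in sample 4 and are no independent control. Early uptake of nitrogen by the sampled cells would raise the same genes and was not tested, and the labels give no difference between these samples.

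Other no-addition samples were singled out once or more: in sample 1 TYS1 by -0.125, DAN4 by 0.159 and the glycolysis and fermentation list by -0.162, and in sample 3 KRS1 by -0.201. Among batch samples 11 cases were found, 6 of them in sample 1: TSL1 at -0.383, ILV3 at -0.318, THI11 at 0.334, THI5 at 0.322, DIP5 at -0.735 and VBA1 at -0.246. In batch sample 2 ARN1 was at -0.125, in sample 3 ARG1 at -0.268, RPA190 at 0.0778 and PAU17 at -0.148, and in sample 4 RPS4A at 0.055.

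A few named genes were called in opposite directions with ammonium and valine, and the difference itself was called, as such opposite calls nearly ensure. It was -2.31 for GDH2 (adjusted p = 1.37e-09), -0.947 for VBA1 (4.12e-06) and -1.21 for OPT2 (1.04e-07), each lower with ammonium in 3 of 3 samples than in any valine sample.

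The library with contradictory labels, which no comparison used, was placed on a scale from valine at 0 to ammonium at 1. It lay at 1.08, ammonium samples between 0.964 and 1.04, and valine samples between -0.0384 and 0.0348. The scale used the 28 genes called with at least a 2-fold difference between these same ammonium and valine samples. Their means also set its ends, so the ranges of these samples are narrow by construction and are no yardstick for the library.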

How the results depend on the processing

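Leaving out 3 samples together and removing the length trend were chosen after the results were seen. Gene counts stayed within 1.5 times of the values reported under median centring, renewed quantile normalization, the dim filter, the highest probe per gene, the slide block, fits of 2 groups alone, either array of ammonium sample 3, the intensity trend and the length trend. With the replicate number as a block 3442, 4058, 4078 and 708 genes were called (the third stage against batch, ammonium, valine, ammonium against valine) and 13, 22, 23 and 8 lists; numbers do not pair these samples, since residual correlations of equal numbers ran from -0.574 to 0.309 and 3 of 14 samples fitted best with their own number. Within slide 1 the counts were 1682, 2477, 2749 and 38, and within slide 2 2387 (the third stage) and 228 (supplements); fewer samples remain there, and a lone sample of a group is assumed to vary like the others. A 2-fold limit left 273, 779, 765 and 28 genes, and between the supplements adjusted p under 0.01 left 435, by construction. Array weights gave 2151 and leaving out the 3 samples apart 1576 genes and 13 lists between the supplements; the cause was not tested. Lists past the threshold numbered 0 in each comparison with an estimated correlation, which widens the test; the rotation test gave 26, 35, 33 and 14 by direction and 36, 36, 36 and 31 in either direction, and it asks another question. Leaving out single samples gave 3303 to 3862, 3836 to 4390, 3927 to 4401 and 501 to 1322 genes (501 without valine 2, 664 without valine 1), 11 to 14, 22 to 23, 22 to 25 and 8 to 13 lists (13 without ammonium 2), and 3366 to 3780 shared calls. No called gene changed direction in any setting. Named genes that turned were all uncalled. Within slide 1, ammonium minus valine gave HXT6 -0.27, ILV5 0.22, MEP2 -0.084, THI4 0.050 and TSL1 -0.080; within slide 2, no addition minus batch gave HXT1 -0.040, LYS20 0.053 and PDC1 -0.047, valine GAP1 0.026, and ammonium minus valine ATF1 0.086 and ILV5 0.10. Array weights gave ATF1 0.011, HXT6 -0.16, ILV5 0.13, MEP2 -0.0015 and TSL1 -0.017 between the supplements, quantile normalization ATF1 0.0020 and the slide 2 array of ammonium 3 ATF1 0.033. Leaving out single samples, no addition minus batch ranged from -0.18 to 0.043 for HSP26, -0.037 to 0.024 for ATF1 and -0.032 to 0.056 for HXT1; ammonium minus no addition from -0.0028 to 0.26 for BAT2 and -0.13 to 0.00091 for PDC1; and ammonium minus valine from -0.038 to 0.030 for ATF1, -0.044 to 0.12 for MEP2, -0.0062 to 0.12 for PDC1, -0.18 to 0.27 for HXT6, -0.17 to 0.24 for ILV5 and -0.044 to 0.39 for TSL1. Such omissions ended the call of a named gene in 37 cases and gave one in 9, and for lists in 10 and 25. Without the 3 samples apart HSP26 was 0.043, BAT2 -0.0028, PDC1 0.00091, HXT6 -0.20, ILV5 0.16 and TSL1 -0.11, and without the length trend ATF1 was 0.045 and MEP2 0.011 against batch. The cause was not tested. For central nitrogen metabolism with valine the rotation test pointed lower (median 0.30, adjusted p = 9.70e-04) where camera pointed higher without passing; directions of lists past no threshold were not followed otherwise. Array signal came without background or detection flags, so low signals compress fold changes by an amount that cannot be given.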

Other observations

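Among the tests below, the comparison of slides for ammonium sample 2 was chosen after the result was seen, as were the counts of reversed calls with separate controls, the 4 added gene lists and the genes named from them and from lists that passed nowhere. These lists were written around genes already seen to move, so no p is given for them. Of 18 cell separation and cell wall genes 17 were higher in the third stage than in batch, with a median of 1.68, among them CIS3 (2.89), DSE2 (2.69), CWP1 (2.65) and TOS1 (2.37). With ammonium 12 of them rose and 3 fell (median 0.51), with valine 10 rose and 5 fell (0.28), and between the supplements 3 were higher and 1 lower with ammonium (0.14). Of 16 beta-oxidation genes 15 fell with ammonium (median -1.10) and 14 with valine (-1.26), among them POT1 (-4.08 and -4.27), CRC1 (-1.92 and -1.67) and FOX2 (-1.56 and -1.44). Of 11 gluconeogenesis and glyoxylate genes 9 fell with each supplement (medians -0.65 and -0.60), such as MDH2 and the activator CAT8 (-1.99 and -1.80). Against batch these lists had medians of 0.01 and 0.01. Of 6 aryl-alcohol dehydrogenases 3 (AAD3, AAD14 and AAD15) rose with each supplement and were higher with ammonium than with valine. AAD10 fell with both (-0.57 and -0.71) and AAD4 with valine (-0.17), while against batch AAD10 and AAD15 were higher and AAD6 lower.

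Some fixed lists passed in no comparison although members moved. Camera's adjusted p (the third stage against batch, ammonium, valine, ammonium against valine) was 0.519, 0.462, 0.866 and 0.547 for central nitrogen metabolism, where GDH3 was at -1.64 with ammonium and -1.63 with valine. It was 0.651, 0.848, 0.403 and 0.0901 for the Ehrlich pathway, where ARO8 rose by 2.17 and 2.56 and PDC5 by 2.93 and 2.95 with ammonium and valine, and PDC6 fell by 2.53 and 1.55. For aroma esters it was 0.651, 0.821, 0.999 and 0.499, with the alcohol acetyltransferase ATF2 at 2.11 and 1.87. For the phosphate regulon it was 0.756, 0.277, 0.053 and 0.227, with the transporter PHO84 at 3.10 and 2.95. Glycolysis and fermentation gave 0.979, 0.442, 0.503 and 0.935, with ENO2 at 0.88 and 0.88, and glycerol genes gave 0.937, 0.0694, 0.121 and 0.357, with GUT2 at -1.73 and -1.83. Meiosis and sporulation gave 0.494, 0.809, 0.893 and 0.201, with SPS100 at -3.27 and -2.89, haploid mating 0.869, 0.707, 0.70 and 0.547, and the mitochondrial genome 0.258, 0.126, 0.0822 and 0.765.

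The library with contradictory labels had AGP1 at 10.70, GDH1 at 12.50 and GDH2 at 10.38. Ammonium samples lay at 10.5 to 10.75, 12.07 to 12.55 and 10.49 to 10.53 in these genes. Valine samples lay at 14.16 to 14.33, 11.12 to 11.3 and 12.6 to 13.04. In these genes the library thus lay in or near the ammonium range and outside the valine range, while its label stays unsettled. Across genes the library's correlation with the ammonium mean was 0.995 and with the valine mean 0.9862, and its difference from these means had an SD of 0.194 and 0.323. Deviations from the group mean correlated at 0.646 across genes between batch sample 1 and valine sample 3, at 0.633 with the length trend removed and at 0.649 with slide as a covariate.

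Ammonium sample 2 lay towards the no-addition samples: on the axis from no addition at 0 to valine at 1 it stood at 0.861, and ammonium samples 1 and 3 at 1.03 and 1.05. Slide is argued against, since sample 1 on the same slide was displaced by -0.019 and sample 2 by -0.178. The trend with gene length is argued against, since the displacement was -0.172 after its removal. Admixture of RNA without added nitrogen is argued against, since the 79 genes at least 4-fold higher with valine were lower by a median of -0.272 (SE 0.0475), while the share of 3.85% that fits the 55 lower genes allows only -0.0567. A culture that had moved less far from the resting state at that sampling remains possible and was not tested.

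The PAU family was higher with ammonium than with valine by a median of 0.387. The trend with gene length is argued against, because the median was 0.333 after its removal, and slide is argued against, because the medians within slides were 0.337 and 0.33. Signal shared between near-identical copies stays open, so the members may be fewer signals than genes. The test planned for it, on 6 DAN and TIR genes of other sequence (median 0.353), decides nothing, since their probes take no part in such sharing. The nitrogen source and time in the run, which differ together between the supplements, were not told apart.

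A hypothesis written before its test was that nitrogen moved genes against the difference between the third stage and the batch. With separate pairs of no-addition samples on each side, the covariance across genes was below 0 in each of 6 splits for both supplements, with -0.0231 as the highest value. With such separate pairs, genes called lower in the third stage and higher with nitrogen numbered 618 to 652 with ammonium and 646 to 677 with valine, where independent calls give 416 to 440 and 416 to 432. Those called higher in the third stage and lower with nitrogen numbered 688 to 754 and 753 to 837 (500 to 535 and 509 to 537 if independent), and those with the same direction in both 733 to 853 and 653 to 716 (913 to 969 and 924 to 955). The correlation with separate pairs was weak, from -0.165 to -0.0668 with ammonium and from -0.216 to -0.116 with valine, and the 6 splits reuse the same samples. The profile as a whole did not return towards the batch. Arrays with a supplement differed from batch arrays with an SD of 0.77 to 0.89, and no-addition arrays with 0.38 to 0.56. On the axis from no addition at 0 to valine at 1, batch samples lay between 0.0363 and 0.16. The opposed movement therefore holds for part of the genes only.

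In the split of 8 samples into groups of 4, the real grouping of the third stage and the batch called 3582 genes and the highest other 0. Only the real grouping, 1 of 35 splits, reached that count, which is the smallest share possible. A chance division of these samplings is argued against. For each supplement against no addition a chance division of the samplings is argued against in the same way. Only the real grouping, 1 of 35 splits, reached its count, 4224 with ammonium against 3122 at most otherwise and 4242 with valine against 3091. Those high counts came from splits that kept 3 no-addition samples together, which follows from the structure of the samples. These splits concern the spread between samplings only, since the time of the run goes with the condition. They cannot exclude a chance difference between cultures or runs, because samples of each continuous condition came from a running culture. For ammonium against valine the 10 splits are too few for a share under 0.05: 1 split, the real one, called 1023 genes and the highest other 0.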
